A study of Mus musculus with 15 samples.

How the data were processed

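Polyadenylated RNA of lymph node cells enriched for CD8 by magnetic positive selection was sequenced from 15 mouse samples. The mice were 15 weeks old and belonged to 3 genotypes with 5 samples each: C57BL/6N (written WT), cS5Alo and cS5Ahi. Each WT sample pooled the lymph nodes of 2 to 3 mice, per the labels. The labels do not say whether the other samples came from 1 mouse each, so p-values measure the spread between these samples.

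The deposited files hold whole-number counts of reads per gene, 1 file per sample, which the authors did not normalise. Per the submitters' processing notes, cutadapt (version not given in the sources used here), TopHat 1.4.1 and HTSeq 0.6.1p1 were named as tools and mm9 as the genome build. The strand setting of the counting is not given in the sources used here. Each file had 21025 gene entries and 5 summary entries. The summary entries stayed out of library sizes and tests. Reads outside annotated genes made up 23.0 to 40.8% of the reads in a file, and ambiguous reads 0.533 to 0.687%. Gene symbols were matched by transcript accession to a RefSeq table of assembly GRCm38.p6 for 20661 of the entries, and no coordinates are given because that assembly is not the one of the files. T cell receptor V segments were not among the counted genes, so the planned test of their shares was not run.

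Samples were grouped by the genotype and title of their labels. The description of cS5Ahi sample 1 names cS5Alo, whereas its title and genotype say cS5Ahi; it was kept as cS5Ahi. Per the file labels, all cS5Ahi libraries shared 1 flow cell and all WT and cS5Alo libraries another. On the latter, WT 1 and 2 were in lane 2, and WT 3, 4 and 5 and all cS5Alo libraries in lane 3. Flow cell and genotype can therefore not be told apart for cS5Ahi. The counts of 30 pairs of libraries within groups differed by a chi-square of 10.4 to 119 per degree of freedom, so no pair of libraries agreed within sampling noise.

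Reads in genes ranged from 12177642 to 33948416 per library. Counts were normalised with TMM factors in edgeR 4.0.16 under R 4.3.3, after genes of low count were removed by group with filterByExpr (minimum count 10, minimum total 15), which left 11979 genes. Expression levels are given as CPM, the reads of a gene relative to the library size scaled with TMM factors; the salivary score and both covariates for salivary and Y-linked transcripts used CPM without these factors. Logarithms of CPM used a prior count of 2. The common biological coefficient of variation was 0.234. The comparisons cS5Ahi against WT, cS5Alo against WT and cS5Ahi against cS5Alo were contrasts of 1 robust edgeR quasi-likelihood fit over all 15 libraries. A gene was called at a Benjamini-Hochberg adjusted p under 0.05. Fold changes carry the standard error of the fit. Groups of 5 were also compared with two-sided exact permutation tests where stated.

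Gene lists for pathways and cell types were fixed before the data were examined, as were the comparisons, the tests and most of the other settings tried. Camera from limma 3.58.1, with a preset correlation of 0.01 between genes, tested the 37 lists with 3 or more measured members against the other genes, adjusted over the lists of a comparison. It was repeated with a correlation estimated per list. A list of 13 salivary gland transcripts was drawn up after the counts had been seen. Named genes followed a fixed rule for each comparison: Stat5a, Stat5b and the CD8 T cell identity genes; the 6 largest called rises and the 6 largest called falls among genes with at least 10 CPM in the higher group and no overlap between the groups, without receptor and immunoglobulin segments, unnamed genes and pseudogenes; and from every list up to 3 called members with the smallest adjusted p, or up to 2 members of highest CPM where none was called. Some genes that the rule gave are not reported here. Members of near-identical families (Klra9, Klra4, Gzmb and Hbb-b1 among those named) are uncertain, since reads shared between copies may have been split or lost in the counting.

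The fit was tested on simulated counts with changed genes drawn from the real means and depths. For cS5Ahi against WT, on 11829 genes, it recovered 44.8% of genes changed 1.5-fold, 71.6% of those changed 2-fold and 84.8% of those changed 4-fold. For cS5Alo against WT (11846 genes) the shares were 32.8, 76.1 and 83.3%, and for cS5Ahi against cS5Alo (11829 genes) 49.3, 71.6 and 89.4%. False calls made up 2.90, 7.25 and 2.78% of the calls in these comparisons. Genes were drawn independently there, with the same spread in all groups. The real WT libraries varied more, with a mean pairwise correlation of 0.952 against 0.978 in cS5Alo and 0.983 in cS5Ahi. The shares recovered in the real data can therefore differ from these, most of all in comparisons with WT.

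The alternatives were other scaling factors, other filters, DESeq2 1.42.0, limma voom with sample quality weights, a test against a fold of 1.5 (glmTreat), fits on the 10 libraries of a comparison, the replicate number as a block, covariates for B cell and Y-linked transcripts, WT libraries of lane 3 and leaving out each library in turn. After the data had been seen, covariates for salivary transcripts and for reads outside genes were added, as were fits without WT 3 and 4 and with WT 2 and 3, which had Y-linked transcripts as low as cS5Alo, as the WT libraries of cS5Alo against WT. Another scaling moved the median log2 fold change of all genes by at most 0.0874. Transcript length and GC content were medians over the transcripts of a mouse reference annotation matched by gene symbol, with a value for 11690 of the 11979 genes. Figures were drawn with matplotlib 3.10.9.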

Results

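The series measured polyadenylated transcripts in CD8-selected lymph node T cells of 15-week-old mice. WT, cS5Alo and cS5Ahi each contributed 5 libraries. The names cS5Alo and cS5Ahi are read here, from knowledge of the study and not from the labels, as mouse lines that carry an active form of STAT5A at a lower and a higher level. STAT5A is a transcription factor downstream of cytokine receptors such as those of interleukin 2 and interleukin 7. Reads in genes numbered 15050220, 26721115, 13452939, 12177642 and 23114527 in WT 1 to 5, 21572654, 27487785, 20228602, 20527571 and 16059604 in cS5Alo 1 to 5, and 33948416, 30054281, 23894325, 22980440 and 31959901 in cS5Ahi 1 to 5. Reads outside genes were 39.8% in WT 3, 40.8% in WT 4 and 36.8% in cS5Ahi 4, against 23.0 to 30.2% in the other libraries. The leading principal component held 33.8% of the variance and separated the cS5Ahi libraries from the rest, and the next held 15.1%.

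**Figure D1:**
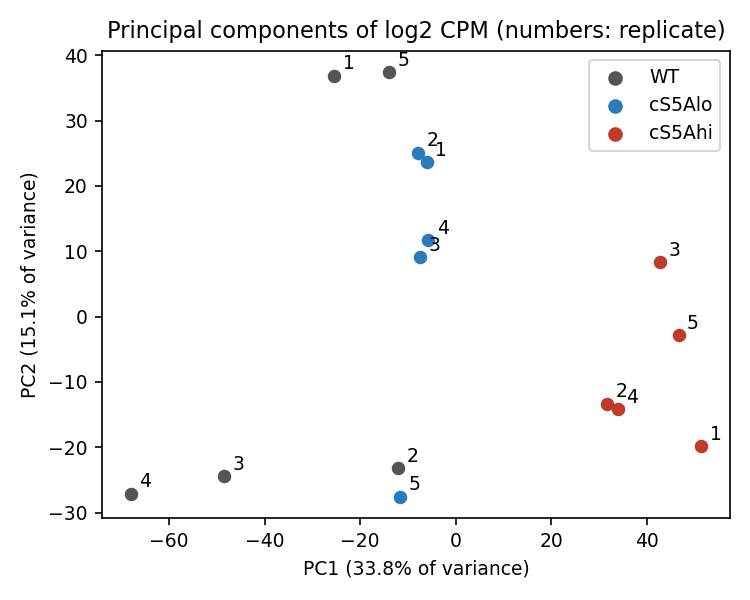
Principal components of log2 CPM of the 15 libraries, 1 point per library with its replicate number, coloured by genotype; the axes give the share of variance (33.8 and 15.1%). The cS5Ahi libraries lie to the right of all others, and WT 2, 3 and 4 lie low on the vertical axis together with cS5Alo 5.

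Stat5a transcripts, which would include those of the transgene as far as its reads map to mouse Stat5a, were lowest in WT and highest in cS5Ahi. Stat5a stood at 82.8 ± 10.2 CPM in WT, 108 ± 7.66 CPM in cS5Alo and 488 ± 90.7 CPM in cS5Ahi (SD, n = 5 each). The ranges of the groups did not overlap, with 71.4 to 95.7 CPM in WT, 100.3 to 117 CPM in cS5Alo and 404 to 635 CPM in cS5Ahi. The difference in mean log2 CPM was 2.55 for cS5Ahi against WT, 2.17 for cS5Ahi against cS5Alo and 0.38 for cS5Alo against WT, each with a two-sided exact permutation p of 0.00794, the smallest that rearranging 5 and 5 libraries can give and also the value after Benjamini-Hochberg adjustment. The edgeR quasi-likelihood test over all genes called Stat5a in both comparisons with cS5Ahi (Benjamini-Hochberg adjusted p = 1.62e-10 against WT and 2.07e-09 against cS5Alo) but not in cS5Alo against WT (log2 fold change 0.38 ± 0.12, adjusted p = 0.292). The neighbouring Stat5b had 129 ± 16.9, 124 ± 12.3 and 121 ± 13.3 CPM in the same order and was not called in any comparison. The counts cannot tell transgene reads from endogenous ones.

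**Figure D2:**
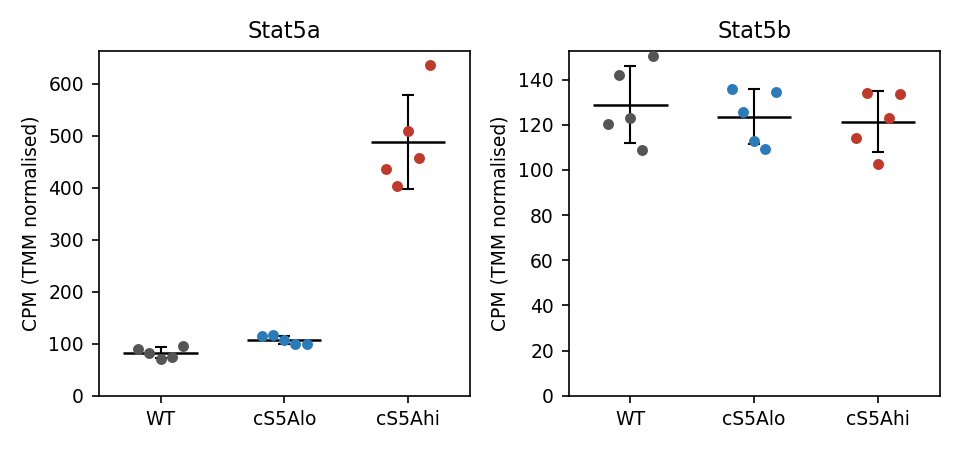
Stat5a and Stat5b in CPM (TMM normalised) by genotype; points are libraries, horizontal lines the means and bars the SD of 5 libraries. Stat5a lay at 404 to 635 CPM in cS5Ahi and at or below 117 CPM in the other libraries, while Stat5b had means of 121 to 129 CPM.

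The comparison of cS5Ahi with WT asks what differs in CD8-selected cells of the line with the high Stat5a level. Gzmb, Klra9 and S1pr5 were among the 6 largest rises under the naming rule. Gzmb, which encodes the cytotoxic protease granzyme B, rose from 3.89 ± 2.01 CPM in WT to 125 ± 44.5 CPM in cS5Ahi (n = 5 each), a log2 fold change of 5.01 ± 0.32 (SE). The natural killer cell receptor gene Klra9 rose from 1.60 ± 1.06 to 103 ± 56.6 CPM, and S1pr5, a receptor for sphingosine 1-phosphate, from 0.238 ± 0.228 to 15.4 ± 2.96 CPM. Map6 (log2 fold change 5.62), Tafa3 (4.68, or 5.40 without WT 5) and Myo6 (4.20) completed the 6 largest rises. The edgeR quasi-likelihood test called 1692 of 11979 genes, 824 higher and 868 lower; 320 of the former and 530 of the latter changed by 2-fold or more. With library size as the sole scaling the split was 603 higher and 1177 lower. The count was 602 against a fold of 1.5, 651 with the salivary score as a covariate and 284 with the B cell score as a covariate, 278 of these among the 1692. The test against a fold of 1.5 asks for a larger change than the main test. Both scores themselves differed between these genotypes, so a fit with either takes up part of the genotype difference. A call lost in such a fit therefore does not show where the transcripts came from.

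Genes of memory CD8 T cells rose as a group in cS5Ahi. Of the 20 measured members 12 rose, 1 fell and 7 were not called, and the counts adjusted over the list alone were also 12 and 1. The chemokine receptor gene Ccr2 went from 6.89 ± 1.92 CPM in WT to 98.8 ± 12 CPM, Samd3 from 22.0 ± 5.57 to 142 ± 24.1 CPM, and Il18r1, which encodes a chain of the interleukin 18 receptor, from 76.9 ± 8.25 to 278 ± 13.1 CPM. Of 34 effector and cytotoxic genes 17 rose, or 19 higher and 1 lower when adjusted over the list alone; Lgals1 was at 80.3 ± 19.0 CPM in WT and 376 ± 80.8 CPM in cS5Ahi. Camera put both lists above the other genes (adjusted p = 6.65e-28 and 5.69e-20), and both calls held with an estimated correlation (adjusted p = 0.000691 and 0.0011). Cd8a, a chain of the selected surface protein, stood at 2346 ± 172 and 2450 ± 184 CPM and was not called.

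**Figure D3:**
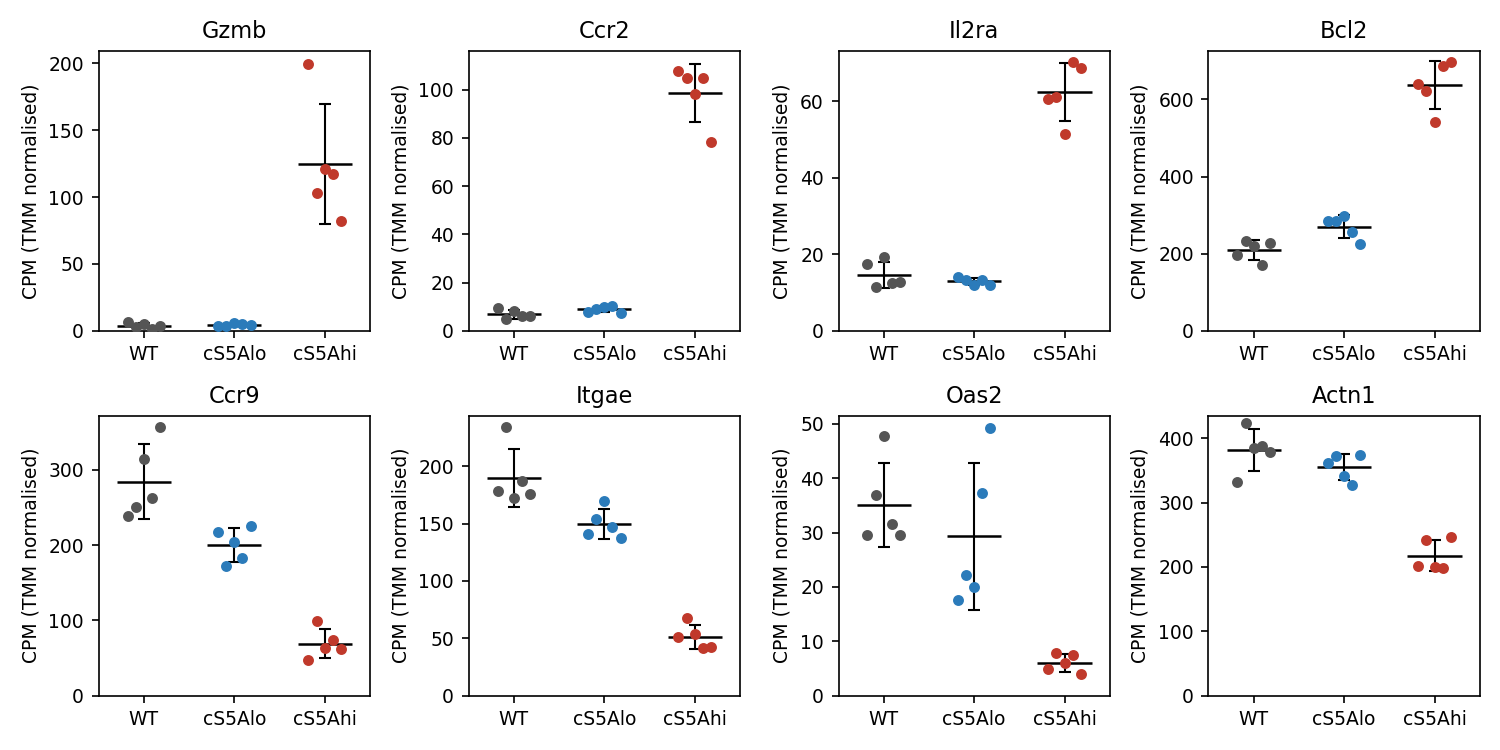
Levels of 8 named genes in CPM (TMM normalised, axes from 0) by genotype; points are libraries, lines means and bars the SD of 5 libraries. Gzmb, Ccr2, Il2ra and Bcl2 were higher in every cS5Ahi library than in any other library, and Ccr9, Itgae, Oas2 and Actn1 were lower.

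Known target genes of STAT5 and cytokine receptor genes also rose in cS5Ahi. Of 24 STAT5 target genes 13 rose and 1 fell, or 15 and 2 when adjusted over the list alone. Il2ra, the alpha chain of the interleukin 2 receptor, rose from 14.7 ± 3.38 to 62.4 ± 7.52 CPM, and the survival gene Bcl2 from 210 ± 25.8 to 637 ± 62.3 CPM. Of 26 cytokine receptor genes 11 rose and 3 fell, with the same numbers when adjusted over the list alone. The 2 lists were called by camera (adjusted p = 4.72e-14 and 6.50e-07) and with an estimated correlation (adjusted p = 0.00145 and 0.0112). Several lists share members. Il2ra is on both of these, Bcl2 is also on the memory and BCL2 family lists, Gzmb on the effector list and Il18r1 on the memory and receptor lists. The calls of these lists are therefore not independent of each other. Among 18 genes of JAK-STAT negative feedback 4 rose, in both counts, including Cish (7.40 ± 2.42 to 17.2 ± 4.27 CPM) and Socs1 (25.1 ± 9.36 to 43 ± 11.7 CPM), but the list was not called (adjusted p = 0.106). It passed without WT 3 and 4 and with the B cell score as a covariate (adjusted p = 0.0391 and 0.0256; 0.0256 to 0.192 over all other settings tried). The edgeR call of Socs1 was lost without WT 1, 2 or 3 or cS5Ahi 3, 4 or 5 (adjusted p = 0.0607 to 0.0915; 0.00716 to 0.687 over all other settings tried). The STAT family had 2 higher and 2 lower of 7 in both counts, a negative median (-0.09) and a positive mean (0.27), and was not called (adjusted p = 0.121). This list holds Stat5a itself (log2 fold change 2.56), which raises its mean. Of 14 BCL2 family genes 4 rose and 1 fell in both counts (adjusted p = 0.00704, or adjusted p = 0.0616 with an estimated correlation and 0.0891 without WT 2). Over all other settings tried the adjusted p of this list ranged from 0.00372 to 0.0891. Bcl2l11, which promotes cell death, rose from 92.7 ± 8.60 to 171 ± 14.3 CPM. With the B cell score as a covariate its edgeR adjusted p was 0.076 (8.32e-12 to 0.076 over all other settings tried) and its log2 fold change 0.645 against 0.884.

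Genes of naive T cells and genes induced by interferon fell in part. Ccr9, a homing receptor, fell from 285 ± 49.5 CPM in WT to 69.0 ± 19.3 CPM in cS5Ahi, Actn1 from 381 ± 32.5 to 218 ± 24.5 CPM and Btg1 from 554 ± 23.9 to 350 ± 24.7 CPM; against a fold of 1.5, Actn1 and Btg1 had edgeR adjusted p = 0.0743 and 0.58 (1.62e-15 to 0.0743 and 3.21e-19 to 0.58 over all other settings tried). Of 26 naive and quiescence genes 6 fell and 2 rose, or 7 and 2 when adjusted over the list alone; camera gave adjusted p = 0.00704, and adjusted p = 0.22 with an estimated correlation. Of 48 interferon-stimulated genes 15 fell and 1 rose, or 21 and 1 when adjusted over the list alone. Oas2 fell from 35.1 ± 7.72 to 6.07 ± 1.65 CPM and Usp18 from 45.3 ± 3.39 to 25.4 ± 3.73 CPM; against a fold of 1.5, Usp18 had edgeR adjusted p = 0.144 (1.23e-07 to 0.144 over all other settings tried). This list had adjusted p = 1.63e-07, and adjusted p = 0.247 with an estimated correlation. Among 18 immediate early and stress genes 7 fell and 2 rose, or 8 and 2 when adjusted over the list alone; Egr1 fell from 99.7 ± 16.8 to 38.4 ± 11.5 CPM and Nr4a1 from 24.5 ± 4.31 to 9.60 ± 3.59 CPM (list adjusted p = 0.00213; adjusted p = 0.141 with an estimated correlation).

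Among surface receptors and adhesion genes, members moved both ways. The integrin gene Itgae fell from 190 ± 25.5 to 51.3 ± 10.6 CPM and Itgb1 rose from 79.1 ± 6.53 to 198 ± 15.8 CPM. Of 30 chemokine receptor and adhesion genes 7 rose and 8 fell, or 8 and 10 when adjusted over the list alone; the median (-0.14) and the mean (0.22) differed in sign and the list was not called (adjusted p = 0.16). Of 25 inhibitory receptor and exhaustion genes 3 rose and 6 fell, or 5 and 11 when adjusted over the list alone, without a call (adjusted p = 0.384). Entpd1, which encodes the ectonucleotidase CD39, rose from 2.40 ± 0.469 to 29.5 ± 2.76 CPM and Nt5e, which encodes CD73, from 49.6 ± 6.30 to 94.9 ± 4.99 CPM. Of 8 CD8 identity genes Gata3 alone was called, at 34.2 ± 5.34 and 48.7 ± 5.69 CPM, and 1 was higher and 1 lower when adjusted over the list alone. The list was not called (adjusted p = 0.959, with a median of -0.04 and a mean of 0.00360). It also holds Cd3 chain genes and Zbtb7b, a gene of the CD4 T cell list too, so it is not specific to CD8 T cells. The call of Gata3 was lost without WT 1, WT 3, cS5Ahi 4 or cS5Ahi 5 (edgeR adjusted p = 0.0534 to 0.0733; 0.00910 to 1 over all other settings tried). Of 31 lymphoma oncogenes and suppressors 4 rose and 8 fell, or 4 and 10 when adjusted over the list alone, without a call (adjusted p = 0.0948). The transcription factor gene Irf4 fell from 43.4 ± 8.91 to 17.4 ± 4.79 CPM, with edgeR adjusted p = 0.0552 under the B cell covariate (1.06e-10 to 0.0552 over all other settings tried). Its log2 fold change was -1.048 with that covariate and -1.315 without it.

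Some genes on the lists of proliferation and biosynthesis rose, most did not pass the test, and the lists were called with the preset correlation alone. Of 43 DNA replication genes 10 rose, or 15 when adjusted over the list alone, among them Pole (13.1 ± 2.60 to 22.2 ± 3.86 CPM) and Mcm4 (105 ± 8.80 to 137 ± 9.93 CPM). Of 56 mitosis genes Racgap1 and Hmgb2 rose, or 1 gene when adjusted over the list alone; the call of Hmgb2 was lost without WT 3, WT 4 or cS5Ahi 4 (edgeR adjusted p = 0.0583 to 0.0688; 0.000497 to 1 over all other settings tried). The mean log2 CPM of the mitosis list was 3.85 in WT 5, 2.94 to 3.17 in the other WT libraries and 3.43 to 3.76 in cS5Ahi. Of 39 MYC target and ribosome biogenesis genes 11 rose (18 when adjusted over the list alone), of 47 ribosomal protein genes 6 (7), and of 21 glycolysis genes 7 rose and 1 fell (8 and 1). Tfrc, the transferrin receptor, was at 42.7 ± 6.92 and 70.3 ± 9.86 CPM and the phosphofructokinase gene Pfkp at 57.5 ± 5.78 and 93.6 ± 9.36 CPM. Camera called these 5 lists with adjusted p = 9.53e-06, 0.00704, 4.00e-06, 0.00197 and 0.00891 in this order, against adjusted p = 0.247, 0.654, 0.128, 0.641 and 0.128 with an estimated correlation. Without WT 3 and 4 the calls of the mitosis and ribosomal protein lists were lost (adjusted p = 0.0833 and 0.101; 2.49e-05 to 0.654 and 2.06e-06 to 0.641 over all other settings tried). Against a fold of 1.5 and with the B cell score as a covariate the calls of Pole, Mcm4, Racgap1, Tfrc and Pfkp were lost. Their log2 fold changes were 0.76, 0.39, 0.57, 0.72 and 0.70, and 0.59, 0.23, 0.27, 0.61 and 0.49 with that covariate. Mcm4 and Racgap1 lay below a fold of 1.5 from the outset, so the test against that fold could not call them. Over all other settings tried the edgeR adjusted p of these genes ranged from 0.000148 to 0.459, 0.000339 to 1, 0.000141 to 1, 7.25e-06 to 0.499 and 3.27e-10 to 0.418.

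Transcripts typical of other cells moved with the genotype. Of 21 B cell genes 17 were lower in cS5Ahi than in WT (18 when adjusted over the list alone), with Cr2 at 13.6 ± 6.80 CPM in WT and 3.12 ± 1.08 CPM in cS5Ahi. The mean log2 CPM of the B cell list was 3.34 to 5.19 in WT, 3.92 to 4.55 in cS5Alo and 2.10 to 3.51 in cS5Ahi (two-sided exact permutation p = 0.0159 for cS5Ahi against WT, 0.0476 adjusted over 6 comparisons of marker scores). Of 16 dendritic cell genes 10 fell (12 when adjusted over the list alone), including Flt3, and the B cell and dendritic cell lists had adjusted p = 3.48e-15 and 1.39e-07, or adjusted p = 0.132 and 0.141 with an estimated correlation. Of 18 macrophage and monocyte genes Ccr2 alone was called, and the list was not (adjusted p = 0.323). Without WT 2 or cS5Ahi 3 and in the rank test it was called as lower (adjusted p = 0.00603, 0.0485 and 0.000344), but with the B cell score as a covariate it was called as higher (0.00166; 0.000344 to 0.924 over all other settings tried). Of 14 natural killer and innate-like genes 6 rose and 2 fell (6 and 3 when adjusted over the list alone; list adjusted p = 0.00558, or adjusted p = 0.244 with an estimated correlation). Klre1 rose from 4.03 ± 1.98 to 28.8 ± 9.77 CPM. With the B cell score as a covariate the log2 fold change of Flt3, which is not on the B cell list, went from -2.62 to -0.65 (edgeR adjusted p = 0.597; 1.58e-10 to 0.597 over all other settings tried). For Cr2 and other genes of the B cell list that fit tests nothing, since they make up the score.

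Among called genes with at least 10 CPM in the higher group and no overlap between the groups, the largest falls were Glycam1, Wfdc12, Dcpp1, Klk1, Insm1 and Mreg. Glycam1, a glycoprotein made by high endothelial venules, was at 54.2 ± 48.4 CPM in WT and 2.10 ± 1.57 CPM in cS5Ahi, a log2 fold change of -4.70 ± 0.76. Wfdc12 was at 19.2 ± 19.2 and 0.947 ± 0.796 CPM, and Dcpp1 at 17.2 ± 23.8 and 0.849 ± 0.70 CPM. WT 3 held 134 CPM of Glycam1, and without it the WT mean was 34.3 CPM and the log2 fold change -4.06. WT 4 held 51.1 CPM of Wfdc12, 59.3 CPM of Dcpp1 and 47.4 CPM of Klk1. Without WT 4 their WT means were 11.2, 6.66 and 5.86 CPM, and their log2 fold changes -3.59, -2.98 and -2.78 against -4.37, -4.35 and -4.05 with all libraries. Without cS5Ahi 4 the cS5Ahi means of Wfdc12 and Dcpp1 were 0.605 and 0.561 CPM, and without cS5Ahi 2 the log2 fold change of Insm1 was -4.06 against -3.43. Wfdc12, Dcpp1 and Klk1 are also on the list of salivary gland transcripts, whose mean log2 level was 3.16 to 6.95 in WT, 1.65 to 5.24 in cS5Alo and 1.12 to 3.01 in cS5Ahi. The edgeR call of Wfdc12 (adjusted p = 0.0399) was lost without WT 1, 3 or 4 or cS5Ahi 1, 2, 3 or 5 (adjusted p = 0.0575 to 0.0989). That of Dcpp1 (adjusted p = 0.0415) was lost without WT 1, 3 or 4 or any single cS5Ahi library (0.0504 to 0.103), and that of Klk1 (adjusted p = 0.0176) without cS5Ahi 1 (0.0512). Over all other settings tried, adjusted p ranged from 0.000786 to 0.797 for Wfdc12, 0.00084 to 0.829 for Dcpp1 and 0.000131 to 0.692 for Klk1. With the B cell score as a covariate Glycam1, Insm1 and Mreg had adjusted p = 0.235, 0.722 and 0.115, the highest of ranges that began at 1.79e-10, 7.82e-06 and 6.52e-16. Their log2 fold changes were then -3.26, -0.93 and -1.51, against -4.70, -3.43 and -3.25. Of the 93 called genes that the naming rule gave for this comparison, 21 lost their call without 1 of the libraries and 59 with the B cell score as a covariate, 3 of the 59 being on the B cell list. Since the B cell score itself differed between the genotypes, these losses cannot tell B cell transcripts from an effect of the genotype.

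**Figure D4:**
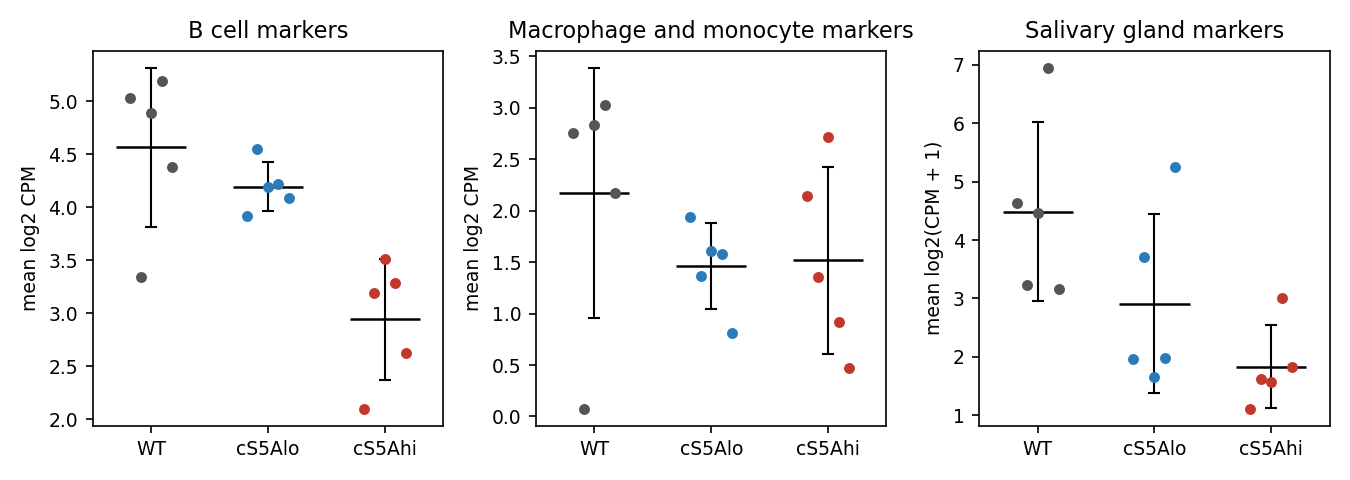
Mean log2 level per library of the B cell list, the macrophage and monocyte list (both log2 CPM) and the salivary gland list (log2 of CPM plus 1, without TMM factors) by genotype; points are libraries, lines means and bars the SD of 5 libraries. The B cell values were 2.10 to 3.51 in cS5Ahi and 3.34 to 5.19 in WT.

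Remaining lists of this comparison were smaller or mixed. Zmat3 rose from 62.0 ± 15.2 to 130.0 ± 6.71 CPM among p53 target genes, of which 2 rose and 1 fell of 20 in both counts (list adjusted p = 0.163). With the B cell score as a covariate Zmat3 had edgeR adjusted p = 0.123 (1.86e-08 to 0.123 over all other settings tried) and a log2 fold change of 0.86 against 1.07. Cell cycle brakes had 2 lower of 13, Btg1 and Cdkn2b (1 higher and 2 lower when adjusted over the list alone; list adjusted p = 0.452), and the call of Cdkn2b was lost under the B cell covariate (adjusted p = 0.923; 0.000527 to 0.923 over all other settings tried). Of 33 T cell receptor signalling genes 3 rose (1 when adjusted over the list alone; list adjusted p = 0.883). The oxidative phosphorylation (1 higher of 44), cholesterol synthesis (1 lower of 23), fatty acid oxidation (0 of 18), unfolded protein response (2 higher, 1 lower of 25) and chromatin lists (1 higher, 3 lower of 40) were not called (adjusted p = 0.137, 0.498, 0.731, 0.323 and 0.364), and adjusted over the list alone the counts were 0, 0, 0, 2 and 1, and 1 and 3. Of 6 plasma cell genes Prdm1 and Jchain rose and Irf4 fell (2 and 3 when adjusted over the list alone; list adjusted p = 0.966, with an upward test but a median of -0.74 and a mean of -0.10), and Jchain, the joining chain of antibody polymers, was at 9.94 ± 4.64 CPM in WT and 47.4 ± 19.1 CPM in cS5Ahi. Of the lists of CD4 T cells, erythroid cells and platelets, stroma and endothelium, and double-positive thymocytes, 4 of 10, 3 of 5, 2 of 7 and 4 of 7 genes fell (4, 3, 4 and 4 when adjusted over the list alone). These lists were lower (adjusted p = 0.00954, 0.0364, 0.00891 and 0.00704), but not with an estimated correlation (adjusted p = 0.0766, 0.247, 0.14 and 0.244). WT 5 stood apart for the thymocyte list, with a mean log2 CPM of 5.88 against 2.70 to 3.53 in the other WT libraries. Cd4 was at 84.7 CPM there and at 1.08 to 12.5 CPM in the other WT libraries, and Aqp11 at 40.9 against 0.159 to 1.77 CPM. Without WT 5 the log2 fold changes of Cd4 and Aqp11 were -1.34 and -1.35, against -3.04 and -4.84 with all libraries. The edgeR call of Cd4 was lost without WT 5 or any single cS5Ahi library (adjusted p = 0.0529 to 0.0873; 0.002 to 0.723 over all other settings tried), and that of Aqp11 without WT 5 or cS5Ahi 1, 3 or 5 (adjusted p = 0.0519 to 0.15; 0.00411 to 0.378). The call of the erythroid and platelet list was lost without WT 4, WT 5 or cS5Ahi 2 (adjusted p = 0.0799, 0.0522 and 0.0907; 0.0101 to 0.504 over all other settings tried). Without both WT 3 and WT 4 this list and the stroma list were not called (0.0933 and 0.0848; 0.00289 to 0.459 for stroma over all other settings tried). Sex-linked genes were not called (list adjusted p = 0.949), and the 2 measured neutrophil genes, Cxcr2 and Csf3r, were too few for a test.

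The comparison of cS5Ahi with cS5Alo asks what differs between the lines of higher and lower Stat5a level. Among called genes with at least 10 CPM in the higher group and no overlap between the groups, the largest rises were those seen against WT. The Y-linked Eif2s3y, whose values overlapped between the groups, had a log2 fold change of 7.59. Gzmb was at 4.47 ± 0.885 CPM in cS5Alo and 125 ± 44.5 CPM in cS5Ahi (n = 5 each), a log2 fold change of 4.81 ± 0.31, and Myo6 at 5.41 ± 0.743 and 80.7 ± 7.54 CPM. S1pr5 (log2 fold change 5.20), Klra9 (4.98), Tafa3 (4.30) and Map6, whose cS5Alo mean was 0.0267 CPM (0.0152 CPM without cS5Alo 2), rose too. Among the largest falls were Glycam1 (log2 fold change -3.43), Trat1 (-2.52), Ifi27l2a (-2.35), Oas2 (-2.27) and Cxcl16 (-2.12). The edgeR quasi-likelihood test called 1035 genes, 583 higher and 452 lower, of which 258 and 204 changed by 2-fold or more. With library size as the sole scaling the split was 484 higher and 571 lower. The count was 262 against a fold of 1.5, 350 with the B cell score as a covariate and 2546 with limma voom. With the B cell score as a covariate Glycam1 and Cxcl16 were not called (edgeR adjusted p = 0.286 and 0.677, the highest of ranges that began at 1.60e-05 and 0.00154).

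The gene groups that rose in cS5Ahi against cS5Alo were again those of memory and effector cells, STAT5 targets and cytokine receptors. Of 20 memory genes 12 rose and 1 fell (13 and 3 when adjusted over the list alone), of 34 effector genes 17 rose (20 higher and 3 lower), of 24 STAT5 targets 15 rose (17) and of 26 cytokine receptor genes 8 rose and 2 fell (11 and 2). Il2rb, the beta chain of the interleukin 2 receptor, rose from 323 ± 54.8 to 825 ± 60.1 CPM and the lectin receptor gene Klrc1 from 3.47 ± 1.44 to 38.5 ± 13 CPM. Bcl2 rose from 270 ± 29.4 to 637 ± 62.3 CPM and Bcl2l1, another survival gene, from 14.4 ± 4.16 to 33.6 ± 4.09 CPM; of 14 BCL2 family genes 4 rose (6 higher and 1 lower when adjusted over the list alone). Of 20 p53 target genes 4 rose and 1 fell (8 and 1). These 6 lists had adjusted p = 2.56e-26, 2.84e-23, 4.50e-20, 9.82e-08, 2.49e-05 and 0.00322, and were called with an estimated correlation (adjusted p = 0.000688, 0.000787, 0.000615, 0.0051, 0.00358 and 0.0333). They share genes such as Bcl2, which is on the memory, STAT5 target and BCL2 family lists, so the 6 calls are not independent.

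Some interferon-stimulated and naive T cell genes fell in cS5Ahi against cS5Alo. Of 48 interferon-stimulated genes 13 fell (21 when adjusted over the list alone), including Irf7 (130.2 ± 23.0 to 73.1 ± 8.71 CPM) and Usp18 (50.04 ± 9.29 to 25.4 ± 3.73 CPM). Of 26 naive and quiescence genes 5 fell (2 higher and 9 lower when adjusted over the list alone), including Ccr9 (201 ± 22.6 to 69.0 ± 19.3 CPM). The lists had adjusted p = 8.90e-10 and 0.00742, or adjusted p = 0.202 for both with an estimated correlation, and medians of -0.36 and -0.015. Against a fold of 1.5, Irf7 had edgeR adjusted p = 0.257 (2.27e-07 to 0.257 over all other settings tried). Of the identity genes Cd3d and Cd3g, chains of the T cell receptor complex, fell (475 ± 45.3 to 368 ± 37.5 CPM and 648 ± 54.9 to 508 ± 46.4 CPM). These edgeR calls were lost without 8 of the 10 libraries for Cd3d, all but cS5Alo 5 and cS5Ahi 3 (adjusted p = 0.0549 to 0.114). For Cd3g they were lost without cS5Alo 1, 2, 3 or 4 or cS5Ahi 1, 2 or 5 (adjusted p = 0.0608 to 0.109). Over all other settings tried the adjusted p ranged from 0.00257 to 1 for Cd3d and from 0.00241 to 1 for Cd3g. Runx3 and Gata3 of the same list were higher when adjusted over the list alone (edgeR adjusted p = 0.0348 and 0.026), and camera did not call the list. Of the 78 called genes that the naming rule gave here, 14 lost their call without 1 of the libraries and 36 with the B cell score as a covariate, 3 of the 36 being on the B cell list. The B cell score itself differed between these genotypes too.

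Further lists of this comparison were called with the preset correlation alone. JAK-STAT negative feedback had 3 higher of 18 (4 when adjusted over the list alone), DNA replication 3 of 43 (7), MYC targets 6 of 39 (9) and glycolysis 5 of 21 (6). Of 56 mitosis genes 3 rose and 1 fell, in both counts; Mki67, a proliferation marker, was at 48.5 ± 21.7 and 95.8 ± 17.7 CPM, and its edgeR call was lost without cS5Alo 1, 2 or 3 or cS5Ahi 1, 2 or 3 (adjusted p = 0.0602 to 0.0838; 0.000461 to 0.459 over all other settings tried). Camera gave these 5 lists adjusted p = 0.0185, 0.000144, 0.000109, 0.00231 and 0.000175, against adjusted p = 0.0653, 0.371, 0.158, 0.0614 and 0.52 with an estimated correlation. Chemokine receptor and adhesion genes (7 higher, 4 lower of 30; 8 and 7 when adjusted over the list alone) had adjusted p = 0.0216, or adjusted p = 0.158 with an estimated correlation, with a negative median (-0.04) and a positive mean (0.31). That call was lost without cS5Alo 5 or cS5Ahi 2 (adjusted p = 0.0574 and 0.0536), and in the rank test it was lost with the direction turned downward (0.888; 0.00289 to 0.888 over all other settings tried). Of 14 natural killer genes 5 rose (6 when adjusted over the list alone; adjusted p = 0.000573, or adjusted p = 0.158 with an estimated correlation). Of 21 B cell genes 14 fell (1 higher and 19 lower when adjusted over the list alone; adjusted p = 2.88e-12, or adjusted p = 0.158 with an estimated correlation) and of 16 dendritic cell genes 3 (4; adjusted p = 9.51e-05, or adjusted p = 0.235 with an estimated correlation). The B cell score differed by -1.25 (two-sided exact permutation p = 0.00794, the smallest possible; 0.0476 adjusted over 6 comparisons).

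In cS5Ahi against cS5Alo, some lists without a call passed when 1 library was left out. Genes of CD4 T cells were lower without cS5Alo 4 or cS5Ahi 2 (adjusted p = 0.0469 and 0.0263, against 0.0608 with all libraries), and genes of erythroid cells and platelets without cS5Alo 1 or 4 (0.0486 and 0.0239, against 0.0797). Those of double-positive thymocytes were lower without cS5Alo 1, cS5Alo 4, cS5Ahi 2 or cS5Ahi 3 (0.0486, 0.0469, 0.0444 and 0.0432, against 0.0538), and oxidative phosphorylation genes without cS5Alo 5 or cS5Ahi 3 (0.0151 and 0.0384, against 0.162). The STAT family, which holds Stat5a itself, was higher without cS5Ahi 1 (0.0484, against 0.0766). Macrophage genes and sex-linked genes were higher without cS5Ahi 5 (0.0417 and 0.0455, against 0.293 and 0.153). The macrophage list holds Ccr2, a gene of the memory list too, with means of 8.92 CPM in cS5Alo and 98.8 CPM in cS5Ahi. With Ccr2 left out and all libraries kept, the mean log2 CPM of the macrophage list differed by -0.14 (two-sided exact permutation p = 0.77). Over all other settings tried, the adjusted p of these 7 lists ranged from 0.0263 to 0.291, 0.0213 to 0.672, 0.0432 to 0.371, 0.0151 to 0.808, 0.0484 to 0.792, 1.29e-06 to 0.945 and 0.0455 to 0.411. With all libraries and an estimated correlation none of the 7 was called by camera (adjusted p = 0.158, 0.372, 0.371, 0.808, 0.202, 0.833 and 0.411). Of 5 sex-linked genes Eif2s3y and Kdm5d were called as higher (4 genes when adjusted over the list alone). Y-linked transcripts summed to 195 to 251.5 CPM in cS5Ahi 1, 2 and 3, to 1.5 and 0.61 CPM in cS5Ahi 4 and 5, and to 0.243 to 2.29 CPM in the cS5Alo libraries. Both edgeR calls were lost without any single cS5Alo library or cS5Ahi 1, 2 or 3 (adjusted p = 0.0749 to 0.11 and 0.0829 to 0.114; 0.00015 to 0.538 and 2.06e-05 to 0.537 over all other settings tried).

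The comparison of cS5Alo with WT asks what differs in the line with the lower Stat5a level, and no gene passed the test over all genes. Il18r1 was at 76.9 ± 8.25 CPM in WT and 108 ± 18.6 CPM in cS5Alo (n = 5 each) and Bcl2 at 210 ± 25.8 and 270 ± 29.4 CPM. Irf4 was at 43.4 ± 8.91 and 25.4 ± 3.80 CPM. The edgeR quasi-likelihood test called 0 of 11979 genes (smallest adjusted p = 0.219), with 1356 genes at an unadjusted p under 0.05 where 599 would be expected by chance. That excess does not show an effect of the genotype, since genes vary together between libraries. A split of the same libraries that mixed the genotypes gave 3063 called genes. DESeq2 called 93 genes (34 higher, 59 lower) and limma voom 0. Y-linked transcripts summed to 0.243 to 2.29 CPM in the cS5Alo libraries, 0.212 to 0.411 CPM in WT 2 and 3, and 67.0 to 202 CPM in WT 1, 4 and 5; against WT 2 and 3 edgeR called 101 genes, a setting chosen after the data had been seen. Without WT 1 it called Amdhd1 (adjusted p = 0.0386), without WT 2 Laptm4b (0.0481) and without cS5Alo 5 Clec2d, Dnmt3a, Fam168a and Mcoln2 (0.0311 each), genes named after their values were seen.

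Of the gene lists, memory genes, ribosomal protein genes and oxidative phosphorylation genes were higher in cS5Alo than in WT by camera with the preset correlation. For memory genes 5 of 20 were higher when adjusted over the list alone (including Il18r1, Bcl2, Eomes and Samd3, named after their values were seen) and 0 over all genes tested. Of 47 ribosomal protein genes 0 were called in either count; Rps20 was at 6429 ± 749 and 7505 ± 938.9 CPM and Rps24 at 5444 ± 529 and 6913 ± 1141 CPM. The 3 lists had adjusted p = 0.000581, 6.05e-09 and 3.65e-07, and adjusted p = 0.324, 0.5 and 0.407 with an estimated correlation. The lists of immediate early genes, lymphoma genes, B cells, macrophages, dendritic cells, stroma and sex-linked genes were lower (adjusted p = 6.06e-05, 0.00573, 0.000579, 0.000579, 0.000579, 0.00702 and 0.0267), and adjusted p = 0.324, 0.324, 0.571, 0.569, 0.425, 0.324 and 0.407 with an estimated correlation. When adjusted over the list alone, Egr1 and Nr4a1 were lower among the immediate early genes and Irf4 among the lymphoma genes, the former pair named after their values were seen. Of 5 sex-linked genes 4 were lower when adjusted over the list alone. The sex-linked call was lost without WT 1, 4 or 5 or cS5Alo 5 (adjusted p = 0.0816, 0.0517, 0.163 and 0.122), and those of macrophages and dendritic cells without cS5Alo 5 (0.0639 and 0.0741). Over all other settings tried these 3 lists had adjusted p = 0.00159 to 0.407, 1.67e-10 to 0.569 and 4.67e-06 to 0.425. Without WT 3 and 4, a setting chosen after the data had been seen, 9 lists were called in place of 10, with 6 shared. The calls of memory, B cell, macrophage and stroma genes were then lost (adjusted p = 0.136, 0.558, 0.268 and 0.194; 6.14e-05 to 0.324, 3.41e-10 to 0.739, 1.67e-10 to 0.569 and 0.0022 to 0.324 over all other settings tried). STAT5 targets were not called (2 higher and 1 lower when adjusted over the list alone; list adjusted p = 0.729).

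Other lists passed in cS5Alo against WT when 1 library was left out. DNA replication genes (adjusted p = 0.0839 with all libraries) were higher without WT 5 or cS5Alo 1, 2 or 3 (0.00721, 0.0496, 0.0124 and 0.0222), and MYC target genes (0.0692) without WT 2 or cS5Alo 2 or 3 (0.0118, 0.044 and 0.0417). Effector genes (0.158) and fatty acid oxidation genes (0.0971) were higher without WT 1 (0.0176 and 0.0424). Genes of double-positive thymocytes (0.0839) were lower without WT 1, 2 or 4 (0.0424, 0.0183 and 0.0442), p53 target genes (0.0839) without WT 1 or 2 (0.0424 and 0.0396), inhibitory receptor genes (0.0919) without WT 4 (0.0488), and mitosis genes (0.509) without cS5Alo 4 (0.0109). Over all other settings tried, these 8 lists ranged from 0.00721 to 0.766, 0.0118 to 0.571, 0.0176 to 0.846, 0.0424 to 0.663, 0.0183 to 0.694, 0.0396 to 0.461, 0.0488 to 0.425 and 0.0109 to 0.969. With all libraries and an estimated correlation none of the 8 was called by camera (adjusted p = 0.697, 0.571, 0.663, 0.663, 0.563, 0.324, 0.425 and 0.969).

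The changes in both lines against WT were compared across genes, which are not independent replicates. Of the genes called in cS5Ahi, 462 were higher and 340 lower against both WT and cS5Alo, where independent lists would share 40.1 and 32.8 genes; both comparisons use the same cS5Ahi libraries. With 0 calls in cS5Alo against WT there was no overlap with that comparison to count. Across genes, the log2 fold changes of cS5Ahi and cS5Alo against WT had a Pearson r of 0.611 and the same sign for 69.5% of genes. Simulations drew all 15 libraries anew, WT included, from the means and spread of the WT libraries, so that no group differed. They gave a mean r of 0.509 and the same sign for 66.8%, with 0.532 and 67.9% as the largest of 100 simulations. Genes were drawn independently there, so variation that genes share between real libraries was absent. The range of the simulations is therefore too narrow to judge the observed values. The covariance was 0.167, against a mean of 0.0648 and a largest value of 0.0689 in the simulations. The difference from the mean was 0.102, and the jackknife standard error of the observed covariance over libraries was 0.082. With the WT libraries split between the comparisons, r had a mean of 0.27 (0.095 to 0.376) over 20 splits.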

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

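The tests on B cell genes, on natural killer cell markers, on the flow cell and without WT 3 and 4 were chosen only after the result was seen.

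In 22 of 372 groups of 5 libraries 1 value lay far from the others, with a gap of over 0.71 of the group's range to the nearest one. At 1 in 20, chance would give about 18.6 if the groups had been chosen without regard to their values. Some genes here, such as Amdhd1, Laptm4b and Fam168a, were named because leaving out a single library changed their call. Some lists also share genes, so 18.6 is a rough guide alone. On the scale of log2(CPM + 1), WT 5 stood high for Rag1 (8.48) and Aqp11 (5.39), WT 2 high for Itgae (7.88) and Itgb1 (6.52) and low for Laptm4b (2.19), and WT 1 high for Amdhd1 (0.48) and low for Xist (2.5). Among cS5Alo libraries, number 5 was low for Lgals1 (6.54) and Tyrobp (2.36) and high for Zmat3 (6.32) and Fam168a (5.98), and number 4 was high for Rag1 (0.92). Among cS5Ahi libraries, number 5 was low for Ccr2 (6.31) and Rag1 (0). In mean log2 CPM of lists, WT 5 was high for double-positive thymocytes (5.88) and mitosis (3.85), WT 3 high for inhibitory receptors (3.43), and WT 2 low for macrophages and monocytes (0.076). By the same measure cS5Alo 5 was low for ribosomal protein (10.76), cholesterol synthesis (3.76) and dendritic cell genes (2.03), and cS5Ahi 5 low for interferon-stimulated genes (5.14).

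Other splits of the 10 libraries of a comparison into groups of 5 were drawn, 100 of the 126 possible, the real split included. For cS5Ahi against WT 1 of 100 splits, the real one, gave as many as 1692 genes, and the highest other count was 277. For cS5Ahi against cS5Alo it was again 1 of 100, with 1035 genes in the real split and 0 as the highest other count. In both comparisons 0 other splits drawn reached the real count. A split that mixes the genotypes widens the spread within its groups, so low counts there are partly built in. The real split is also the split by flow cell. For cS5Alo against WT all 100 splits gave at least the 0 genes of the real one, which was certain in advance and tests nothing. The highest other count there was 3063, and 4 other splits gave over 100 genes, each with WT 2, 3 and 4 and cS5Alo 5 in the same group, the libraries that lay low on the vertical axis of the principal component plot, which points to a structure of the samples. Across genes, which are not independent replicates, the loadings on that axis correlated with GC content (Spearman 0.513). Counts of called lists were reached by 6 of 100 splits for cS5Ahi against WT (20 lists, highest other 22). For cS5Alo against WT it was 20 of 100 (10, highest other 14) and for cS5Ahi against cS5Alo 16 of 100 (17, highest other 22). In cS5Ahi against WT, the other splits that reached 20 lists each exchanged a single library between the genotypes. Such splits keep most of the genotype difference. The test therefore does not decide whether chance explains the counts of lists, and chance cannot be excluded.

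Ribosomal protein genes lay above other genes in cS5Alo against WT by a mean log2 excess of 0.25 (SE 0.14). A candidate explanation is the pair of WT libraries with the highest shares of reads outside genes. Without WT 3 and 4 the excess was 0.13 (SE 0.12), and with a trend on transcript length and GC content removed in each library it was 0.21 (SE 0.11). Neither value lay above 0.5 of the original excess by more than its standard error, so neither explanation can be told apart from a difference between the genotypes, which stays untested.

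B cell genes were lower in cS5Ahi than in cS5Alo, and a smaller carry-over of all other cell types together through the CD8 selection is a candidate explanation. The B cell score fell by 1.25 on the log2 scale (two-sided exact permutation p = 0.00794, the smallest possible), and the macrophage score without Ccr2 differed by -0.14 (exact permutation p = 0.77). The test of the difference between both scores gave an exact permutation p of 0.0714 (0.143 adjusted over 6 comparisons), which does not decide, since the macrophage score without Ccr2 ranged from 0.131 to 2.48 in cS5Ahi and from 0.685 to 1.88 in cS5Alo. A difference in B cells between the genotypes stays open too.

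Natural killer cell receptor and cytotoxic genes such as Klra9 and Gzmb were higher in cS5Ahi than in WT, and natural killer cells among the selected cells could bring such transcripts, although selection for CD8 should deplete them. The median log2 fold change of Ncr1, Tyrobp and Fcer1g, which those cells express, was -1.76, the opposite direction; Tyrobp was at 22.8 ± 14.5 CPM in WT and 10.8 ± 5.65 CPM in cS5Ahi, and Fcer1g at 40.6 ± 19.4 and 12 ± 7.91 CPM (edgeR adjusted p = 0.166 and 0.0242). These markers did not rise with Klra9 and Gzmb. However, Ncr1 was near the floor, at 0.975 ± 0.804 CPM in WT and 0.268 ± 0.244 CPM in cS5Ahi (edgeR adjusted p = 0.136). The counts cannot tell which cells the Tyrobp and Fcer1g transcripts came from, so the test does not decide. The flow cell cannot be told apart from the genotype, since 0 WT or cS5Alo libraries shared the flow cell of cS5Ahi. An effect of the genotype on CD8 T cells stays open as a hypothesis.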

How the results depend on the processing

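The fits without WT 3 and 4, against WT 2 and 3 alone, and with covariates for reads outside genes and salivary transcripts were chosen only after the result was seen. For cS5Ahi against WT, 1692 genes became 284 with the B cell score as a covariate (278 shared), 651 with the salivary score (608 shared) and 602 against a fold of 1.5, and lay between 1207 and 2238 under the other settings, leave-one-out fits aside. For cS5Ahi against cS5Alo, 1035 became 350 (328 shared), 2546 with limma voom (1025 shared) and 262 against a fold of 1.5, and otherwise lay between 727 and 1498. For cS5Alo against WT, 0 became 93 with DESeq2 and 101 against WT 2 and 3, and stayed 0 with limma voom and the other settings. Called lists fell from 20, 10 and 17 to 4, 0 and 6 with an estimated correlation, and from 10 to 5 for cS5Alo against WT with the B cell score. Without WT 3 and 4, 4 lists were lost and 1 gained for cS5Ahi against WT, and 4 were lost and 3 gained for cS5Alo against WT (6 of 10 shared). The B cell score lost 6 and gained 3 for cS5Ahi against WT and lost 3 and gained 1 against cS5Alo, the B cell list itself being lost in each by construction, and the rank test lost 4 and gained 2, and lost 3 and gained 1. The result for the list macrophages and monocytes, cS5Ahi vs WT, turned upward with the B cell score (adjusted p = 0.00166; 0.000344 to 0.924 over all other settings), and that for the list chemokine receptor and adhesion genes, cS5Ahi vs cS5Alo, turned downward in the rank test (adjusted p = 0.888; 0.00289 to 0.888). The cause was not tested for any of these. The covariance of both effects moved from 0.167 to 0.0578 in the 7939 genes at 10 CPM or more, and the part expected from the shared WT libraries alone from 0.0731 to 0.0255. Leaving out 1 library gave 1247 (without cS5Ahi 1) to 1905 (without WT 5) genes, 0 to 4, and 769 to 1121, with 19 to 21, 7 to 13 and 17 to 20 lists in the same order; Stat5a differences were 2.45 to 2.61, 0.33 to 0.44 and 2.07 to 2.23. Of the named called genes 29 of 93 kept their call under every setting run for cS5Ahi against WT and 34 of 78 against cS5Alo, and of the called lists 4 of 20, 0 of 10 and 6 of 17. The test against a fold of 1.5, which asks for a larger change, by itself ended 41 of the 93 calls and 37 of the 78. The B cell score, which itself differed between the genotypes, ended 59 and 36. With the replicate number as a block (replicate block) 1252, 0 and 727 genes and 20, 9 and 20 lists were called. For a check of pairing, the group mean of each gene was subtracted from log2 CPM. The remaining deviations of libraries with the same number correlated at -0.164 to 0.187, -0.318 to 0.198 and -0.20 to -0.0713. Of 5 libraries, 0, 1 and 0 correlated best with their own number, so the numbers do not pair the samples. Without that subtraction, libraries of different groups correlated at 0.907 to 0.979. The Y-linked covariate was not run for cS5Alo against WT and cS5Ahi against cS5Alo. At this depth the simulated data gave 32.8 to 49.3% of genes changed 1.5-fold, which limits what a missing call can show.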

Other observations

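The salivary gland list and the fits that use it were chosen only after the result was seen, and no explanation was tested for the values given here.

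WT 5 held transcripts of immature thymocytes at levels not seen in the other 14 libraries. Rag1, part of the recombinase that assembles receptor genes, was at 355 CPM there and at 0 to 0.897 CPM elsewhere. Dntt, which adds nucleotides at the joints of receptor genes, was at 79.7 CPM against 6.21 to 16 CPM, and Cd4 at 84.7 against 1.08 to 12.5 CPM. Cd8a was at 2584 CPM in WT 5 and at 2159 to 2724 CPM in the others.

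Transcripts of salivary glands were found in libraries of each genotype. Bpifa2, a secreted salivary protein, was at 3695 CPM in WT 4, 3227 CPM in cS5Alo 5 and 2228.5 CPM in WT 1, and at 10.6 CPM in cS5Alo 1. In cS5Ahi it ranged from 32.4 to 552 CPM. Smr3a was at 1465 CPM in WT 4, 814 CPM in cS5Alo 5 and 754 CPM in WT 1.

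Sex-linked transcripts differed between libraries of a group. Xist was at 4.67 CPM in WT 1, and at 9.24, 24 and 14.8 CPM in cS5Ahi 1, 2 and 3, where Y-linked transcripts summed to 195 to 251.5 CPM. In cS5Ahi 4 and 5 Xist was at 3429 and 2175 CPM and Y-linked transcripts at 1.5 and 0.61 CPM. WT 4 and 5 held both kinds, with 1829 and 630.2 CPM of Xist and 67.0 and 125 CPM of Y-linked transcripts. All cS5Alo libraries held 1490 to 2429 CPM of Xist and at most 2.29 CPM of Y-linked transcripts. The labels used here give no sex, but WT 1 and cS5Ahi 1 to 3 read as male by these values. WT 2 and 3, cS5Ahi 4 and 5 and all cS5Alo libraries read as female, and WT 4 and 5 as mixed. Sex was thus partly tied to genotype in both comparisons with cS5Alo, where no Y-linked covariate was run. With a Y-linked covariate 1703 genes were called in cS5Ahi against WT, against 1692 without it.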
